A study of Mus musculus with 12 samples.

How the data were processed

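RNA was measured on Illumina bead arrays in splenic B cells of 8-week-old C57BL/6 mice carrying a deletion of 1 E2A allele. Per the labels' protocols, the cells were activated with CD40 ligand (200 ng/ml) and interleukin 4 (5 ng/ml) for 14 h. They were then infected in 2 rounds of 12 h each with a retrovirus carrying E12 and GFP, with lipopolysaccharide (200 ng/ml) added during infection, and left for another 22 h. Some cells then received F(ab')2 antibody against mouse IgM (2.5 μg/ml) for 3 h. Infected cells were purified by their GFP fluorescence on a FACSAria sorter, per the series' design text. Total RNA was taken with Trizol and RNeasy columns, its quality was checked on a Bioanalyser, and biotin-labelled cRNA was made with an Ambion kit. There were 12 arrays in 4 groups of 3: wild-type or mutant E12, each untreated or treated with anti-IgM. Groups came from the sample titles.

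The values analysed were the deposited probe intensity values, which the authors had background-subtracted and normalized on a linear scale. This was read from the values, which reach below 0. The 6 wild-type E12 arrays shared a median of 6.93 or 6.94 and the 6 mutant E12 arrays shared a median of 6.40, so the 2 sets had been normalized separately. The software and methods of background correction and normalization are not given in the sources used here. A table of signals before normalization names its 12 columns in a way that matches no sample label, so those 12 columns were not used here. The design had named limma's neqc for raw signals with detection p values. The values analysed hold neither, so this step was replaced after the values had been seen: all 12 arrays were quantile-normalized together, and log2(value + 50) was taken. This assumes that the authors' normalization kept the order of probes within each array. The offset of 50 shrinks the log2 changes of dim probes. A joint quantile step also removes any difference between the E12 forms that shifts most genes.

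With no detection p at hand, each array's limit of detection was set from the spread of its values below 0, at the level a normal background passes with p 0.01. The limit was 12.9 intensity units in the wild-type E12 arrays and ranged from 15.6 to 15.7 in the mutant E12 arrays. A probe had to exceed it on at least 3 arrays. Of 45281 probes, 34885 had 1 gene symbol, 18 had several and 10378 had none. For 34807 probes the symbol was looked up through the Entrez identifier, which changed 0 symbols. The filter kept 19715 probes, 16267 of them with a symbol. For each gene the probe with the highest mean over the 12 arrays was used, which gave 10050 genes. The probes carry no position here, so no genome coordinates are given.

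Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided), with a mean for each of the 4 groups in 1 fit. Values are log2 changes with the standard error of the fit, from 3 arrays per group. P-values were adjusted by Benjamini-Hochberg over the 10050 genes within each of 5 comparisons, with a threshold of 0.05. The residual degrees of freedom were 8 and the prior added 6.25. The difference of the anti-IgM responses is the interaction term, the response with mutant E12 minus the response with wild-type E12. Where a gene passed the detection limit on 0 of the 3 arrays of a group, its fold is given as a lower bound, computed against that limit.

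The 24 gene lists, 6 of them markers of other cell types, the comparisons and the rule for naming genes were set before the data were examined. The lists hold 450 genes, of which 404 had a named probe and 334 were tested. Lists were tested with limma's camera against all other tested genes, with a preset correlation of 0.01 and, beside it, with a correlation estimated from the data. A list is said to be called here by camera with the preset correlation. A further planned test, limma's fry, asks whether the members of a list moved at all, without regard to other genes. Its directional result is given where it went against camera in the anti-IgM responses. Adjustment was over the 24 lists within each comparison. Member counts are given over all genes tested and adjusted over the list alone. The naming rule was Tcf3 on every array, then the 10 largest rises and the 10 largest falls past the threshold whose groups did not overlap, or all of them where fewer passed. For the difference of responses it was the 10 largest of each sign. It added up to 4 members of each list with the largest change past the threshold, or the 2 with the smallest p where none passed, and a short set of genes given by name, of which Cd79b, Ebf1 and Id3 were measured and are reported. Clone-like symbols were counted but not named.

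The likeness of the responses was described by correlations across genes, and genes are not independent replicates. A slope of the mutant on the wild-type response, corrected for noise, was computed with jackknife errors over arrays. The fit was tested on simulated data of 10050 genes with 50 changed genes at each size. In these it recovered 98% of changes of 1 log2 unit in the wild-type response, 94% in the mutant response and 64% in their difference, and a true slope of 0.3 came back as 0.305. The share of false calls was 2.31%, 9.00% and 4.83%. The simulated noise was independent between genes, with the same spread for a gene on all 12 arrays. The real mutant arrays had a larger spread than the treated wild-type arrays (median SD 0.18 against 0.10). They also shared an axis with 64.7% of the variance of their deviations. The simulated shares may therefore not hold for the real data, least of all for the mutant response and the difference.

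Replicate numbers in the titles were checked as pairs by correlating the deviations of arrays from their group means. Among wild-type E12 arrays, pairs with the same number correlated at 0.289, 0.177 and 0.185. Each was over 0.1, but different-number pairs also reached 0.153 (untreated 2 with treated 3) and 0.121 (untreated 3 with treated 2). Different-number pairs that held a replicate 1 lay between -0.245 and -0.180. Only replicate 1 was thus set apart by number, and pairing of wild-type replicates 2 and 3 was not resolved. Among mutant E12 arrays, the same-number pairs gave 0.608, -0.0455 and 0.547, so the numbers did not pair these by this measure, nor did they across E12 forms. Xist, the RNA of the inactive X chromosome, went the other way among mutant arrays. It differed by at most 0.43 within a number and by at least 0.98 between single arrays of different numbers. Eif2s3y, a gene of the Y chromosome, was lowest in both mutant replicates 2 (8.57 and 8.55), against 9.12 to 9.58 in the other mutant arrays. It did not separate replicates 1 from replicates 3. An axis with 64.7% of the variance of the mutant deviations can mask pairing in the correlations, so they do not settle it. Pairing of the mutant arrays therefore stays open. The planned fit without number as a block was kept, and the fits with it are alternatives. Nothing in the labels says that replicate arrays came from separate animals or cultures. The p-values therefore measure the spread between these samples, which may be technical, and 3 arrays per group limit the precision.

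The alternatives tried were no filter, detection on all 12 arrays, every probe on its own, centring on the 75th percentile, the deposited values without a further step, eBayes with trend and robust options, array weights, replicate number as a block, a fold of at least 1.5, only the 6 arrays compared, and each array left out in turn. Offsets of 32 and 100, cyclic loess and a replicate block within each E12 form were added after the data had been seen.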

Results

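Gene expression was measured in primary mouse B cells that expressed wild-type E12 or a mutant E12 from a retrovirus, with or without 3 h of antigen receptor crosslinking by anti-IgM. E12 is a basic helix-loop-helix transcription factor made from the Tcf3 gene, which is also called E2A. The series title describes the mutant as resistant to calmodulin, a calcium-binding protein that acts downstream of antigen receptor signals. The 4 groups held 3 arrays each: wild-type E12 untreated, wild-type E12 with anti-IgM, mutant E12 untreated and mutant E12 with anti-IgM. Between 18110 and 18124 probes were above the detection limit on each wild-type E12 array, and between 16667 and 16676 on each mutant E12 array. These counts rest on values normalized separately by form, with a limit set from the same values. They therefore do not compare how many genes the cells of each form expressed. Arrays of a group correlated at 0.978 to 0.997 across genes, which are not independent replicates. The median standard deviation of a gene within a group was 0.16, 0.10, 0.18 and 0.18 log2 units in the order given above.

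Tcf3 was detected on all 12 arrays. Its log2 intensity was 10.50, 10.61 and 11.01 with wild-type E12 untreated (mean 10.71 ± 0.27 SD, n = 3) and 11.17, 10.45 and 10.34 with wild-type E12 and anti-IgM (10.66 ± 0.45). With mutant E12 it was 11.91, 12.31 and 12.93 untreated (12.38 ± 0.52) and 11.27, 12.79 and 12.54 with anti-IgM (12.20 ± 0.82). Tcf3 signal was thus higher with the mutant, by 1.68 ± 0.35 (SE) log2 units in untreated cells (adjusted p = 0.00153) and by 1.55 ± 0.35 with anti-IgM (adjusted p = 0.00249). A second Tcf3 probe gave 1.65 and 1.59. Anti-IgM did not change Tcf3 past the threshold in either form (-0.05 and -0.18). Where the probes lie relative to the retroviral insert is not known here, so the shares of the insert and the endogenous gene cannot be separated.

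**Figure D1:**
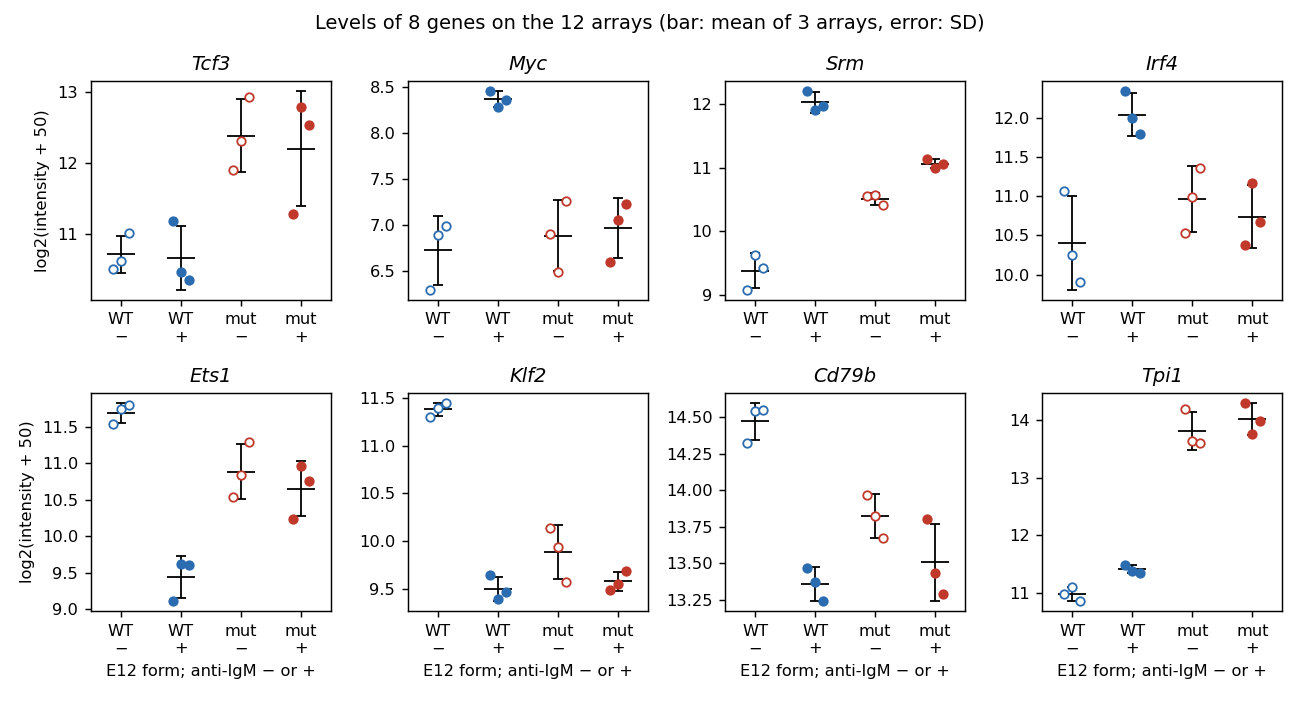
Log2(intensity + 50) of 8 genes on each of the 12 arrays, by E12 form and anti-IgM, with points for arrays, bars for group means and error bars for the SD of 3 arrays. Myc rose with wild-type E12 by 1.64, its change of 0.08 with mutant E12 was not past the threshold, and Tpi1 was higher with mutant E12 by 2.83 in untreated cells.

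The comparison of anti-IgM with no treatment among wild-type E12 cells shows how these cells responded to their antigen receptor. As lists, MYC and ribosome biogenesis genes rose within 3 h and interferon response genes fell (adjusted p = 0.0203 and 0.0358 with an estimated correlation). Ccl4 and Ccl3, chemokines that activated B cells secrete, rose by 3.83 ± 0.53 and 2.50 ± 0.30 log2 units (SE, n = 3 per group; adjusted p = 8.70e-05 and 2.63e-05). Srm, a polyamine synthesis enzyme, rose by 2.65 ± 0.14 and Nop56, a small nucleolar RNA-binding protein of ribosome assembly, by 2.49 ± 0.18. Mxd4, a member of the MAX network that opposes MYC, fell by 2.45 ± 0.18 (adjusted p = 7.28e-07).

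Of 10050 genes, 3148 passed the threshold, 1522 higher and 1626 lower, and 371 rose and 324 fell by at least 1 log2 unit. The values of the 3 treated and the 3 untreated arrays did not overlap for 5056 of the 10050 genes, where chance gives 10%. Among the largest rises were also the tetraspanin Cd63 (2.83 ± 0.19), the urokinase gene Plau (2.83 ± 0.15), the tRNA methyltransferase Trmt61a (2.77 ± 0.12), the cell cycle regulator Rgcc (2.50), the MAP kinase phosphatase Dusp2 (2.27 ± 0.19) and the G-protein signalling regulator Rgs1 (2.26). The largest falls were Snx29 (-2.75), Arhgef18 (-2.56), Mxd4, the interferon-induced GTPase Gbp2 (-2.39 ± 0.25), Amigo2 (-2.38), Ypel3 (-2.35), E2f2 (-2.31 ± 0.15), Abi3 (-2.31), the kinase gene Lrrk2 (-2.27 ± 0.13) and Rnase6 (-2.27). A second probe for Snx29 gave -0.31 and did not pass (adjusted p = 0.147).

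MYC and ribosome biogenesis genes rose almost as a block: 18 of 19 measured members passed upward, with a median of 1.52 and the same 18 adjusted over the list alone (adjusted p = 5.04e-16; adjusted p = 0.0203 with an estimated correlation). Besides Srm and Nop56 these included Nop58 (2.21) and Rrp9 (2.14). Of 23 immediate early and activation genes 10 rose and 0 fell, also adjusted over the list alone, with Dusp2, Fosl2 (1.80), Dusp4 (1.72) and Myc itself (1.64 ± 0.22) leading. That list's median was 0.42 (adjusted p = 0.00133; adjusted p = 0.263 with an estimated correlation). Of 12 glycolysis genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), led by lactate dehydrogenase Ldha (1.25), the glucose transporter Slc2a1 (1.13) and Pgam1 (0.92). Their median was 0.59 (adjusted p = 0.00240; adjusted p = 0.193 with an estimated correlation). Of 17 stress and unfolded protein response genes 8 rose and 2 fell (9 and 2 adjusted over the list alone), among them the mitochondrial chaperone Hspd1 (1.49) and the stress-induced factor Ddit3 (1.20). The median was 0.38 (adjusted p = 0.00240; adjusted p = 0.0726 with an estimated correlation).

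Antigen receptor components and proximal signalling genes went the other way. Of 26 measured, 14 fell and 3 rose (14 and 4 adjusted over the list alone), with a median of -0.54 (adjusted p = 0.00803; adjusted p = 0.0894 with an estimated correlation). The adaptor Bank1 (-1.57), the inhibitory coreceptor Cd22 (-1.25), the kinase Prkcb (-1.20) and Cd79b, a signalling chain of the receptor (-1.11 ± 0.14, adjusted p = 5.45e-05), were among those that fell. B cell transcription factors were mixed, with 9 of 24 lower and 3 higher, the same adjusted over the list alone: Ets1 (-2.25), Klf2 (-1.88) and Pou2f2 (-1.56) fell while Irf4, a factor of B cell activation, rose by 1.63. Their median was -0.29 (adjusted p = 0.0133; adjusted p = 0.304 with an estimated correlation). Other probes for Ets1 gave -0.48 and -0.22, neither past the threshold. Interferon response genes fell in 9 of 15 cases and rose in 0, the same adjusted over the list alone, with Gbp2, Gbp3 (-1.92) and Oasl2 (-1.10) as examples. Their median was -0.39 (adjusted p = 9.97e-04; adjusted p = 0.0358 with an estimated correlation). Of 25 cell cycle genes 8 fell and 2 rose (9 and 2 adjusted over the list alone), with the cyclins Ccnd3 at -1.21 (other probes -0.07 and -0.11, not past the threshold) and Ccnd2 at 0.99. That list's median was -0.32 (adjusted p = 0.0301; adjusted p = 0.263 with an estimated correlation). The call was lost with detection on all 12 arrays (adjusted p = 0.0588) and without untreated wild-type replicate 3 (adjusted p = 0.0578) or treated wild-type replicate 1 (adjusted p = 0.0876).

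Other lists were not called as sets by camera, though members moved. Fry, however, called NF-kB targets as higher (adjusted p = 8.54e-05). It called apoptosis (5.4e-04), calcium (0.0174), antigen presentation (0.0369) and immunoglobulin genes (0.0299) and stromal markers (0.0125) as lower. It called no other list of this and the next paragraph. Of 19 E2A-associated target genes 4 rose and 7 fell (adjusted p = 0.416), including Gfi1 (1.79) and Socs3 (-1.24), while Ebf1 (0.06, adjusted p = 0.779) and Id3 (-0.41, adjusted p = 0.172, or 0.0227 with replicate number as a block within each E12 form) did not pass. Of 19 NF-kB target genes 6 rose, among them Rel (1.06) and Traf1 (1.04), and 4 fell, among them the costimulatory receptor Cd40 (-1.36). Of 23 calcium, calmodulin and NFAT genes 4 rose and 8 fell, with the calcium channel subunit Orai1 at 1.20 and the calcineurin subunit Ppp3ca at -1.31. Of 16 cytokine, chemokine and trafficking genes 6 rose and 4 fell, the chemokine receptor Ccr6 by -1.71. Antigen presentation genes fell in 7 of 20 cases and rose in 1, and this list was called without untreated wild-type replicate 1 (adjusted p = 0.0106 against 0.147). Apoptosis genes fell in 7 of 17 cases, the survival gene Bcl2 by -1.23, and rose in 1. Cholesterol synthesis genes rose in 2 of 14 cases (Cyp51 1.35; adjusted p = 0.0936), and were called as a list without untreated wild-type replicate 2 (adjusted p = 0.0224) or 3 (adjusted p = 0.0247). Plasma cell genes rose in 2 and fell in 2 of 18, and repair genes rose in 1 and fell in 1 of 14 (Ung 0.85). Of 4 immunoglobulin and surrogate light chain genes 1 fell (Vpreb3, -1.30), and the median of 0.12 differed in sign from the mean of -0.20. Median and mean also differed in sign for the repair (-0.07 and 0.04) and plasma cell genes (-0.04 and 0.06) and for the T cell (-0.03 and 0.04), NK cell (0.11 and -0.33) and erythroid markers (0.01 and -0.02). The counts adjusted over the list alone were the same for these lists except for the calcium genes, with 5 higher and 8 lower.

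Among markers of other cells, 2 of 12 myeloid markers fell, the macrophage gene Adgre1 (-1.55) and Mpeg1 (-1.51), and 1 rose, Fcer1g (0.86). Untreated wild-type replicate 1, singled out after its values were seen, carried more of the macrophage lysozyme transcripts, with Lyz1 at 10.45 against a mean of 8.61 in the other 2 arrays and Lyz2 at 8.82 against 7.21. Of 7 T cell markers 2 rose and 1 fell, 1 of 3 NK and cytotoxic markers fell (Prf1, -1.45, with another probe at 0.37), 1 of 5 dendritic markers fell, 0 of 3 erythroid markers passed, and 1 of 3 stromal markers fell (Pecam1, -1.53).

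The same comparison among mutant E12 cells gave far fewer calls. The clearest rises were Fam167a (1.23 ± 0.15 log2 units, SE, n = 3 per group; adjusted p = 0.00433), Ephx1, an epoxide hydrolase (1.17 ± 0.14, adjusted p = 0.00433), and Trmt61a (1.11 ± 0.12, adjusted p = 0.00167). Cd63 rose by 1.19 ± 0.19 and Nop56 by 0.97 ± 0.18 (adjusted p = 0.0253 and 0.0376). Pik3ap1, an adaptor that links the B cell receptor to PI3 kinase, rose by 1.06 ± 0.15 (adjusted p = 0.0136).

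In all, 23 of 10050 genes passed, 19 higher and 4 lower, and 922 had an unadjusted p under 0.05. Treated and untreated arrays did not overlap for 1215 of the 10050 genes, where chance gives 10%. The other named rises were Nxpe2 (1.02), the synaptic scaffold gene Homer1 (1.01), the inflammatory caspase gene Casp4 (0.84) and the myosin gene Myo1e (0.84, with another probe at -0.13). The falls were Smagp (-0.91 ± 0.16), the sugar transporter Slc2a6 (-0.75), Tha1 (-0.68) and Usp3 (-0.59). Ccl4 (2.57 ± 0.53, adjusted p = 0.0591), Ccl3 (1.47, adjusted p = 0.0584), Egr3 (1.33, adjusted p = 0.155) and Rel (0.66, adjusted p = 0.0570) did not pass, nor did Myc (0.08) or Cd79b (-0.31, adjusted p = 0.536).

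MYC and ribosome biogenesis genes rose as a list here too: 1 of 19 passed over all genes and 12 adjusted over the list alone, 0 fell, and the median was 0.49 (adjusted p = 7.01e-14; adjusted p = 0.0320 with an estimated correlation). Cholesterol synthesis genes had a median of 0.25 with 0 of 14 members past the threshold either way, over all genes or adjusted over the list alone (adjusted p = 0.0102; adjusted p = 0.879 with an estimated correlation). Their call was lost with array weights (adjusted p = 0.0933) and without untreated mutant replicate 3 (adjusted p = 0.259) or treated mutant replicate 1 (adjusted p = 0.310). Fry did not call the cholesterol synthesis list (adjusted p = 0.750). Of 26 antigen receptor genes 1 rose (Pik3ap1; 4 adjusted over the list alone) and 0 fell, and the median of -0.02 differed in sign from the mean of 0.07. Immediate early genes had a median of 0.01 with 0 of 23 past the threshold (2 higher and 1 lower adjusted over the list alone). Of these, Egr1, Fos and Dusp1 also varied along an axis shared by the mutant arrays that did not follow treatment, described below. Plasma cell genes had a median of -0.10 and were not called (adjusted p = 0.191), but were without untreated mutant replicate 1 (adjusted p = 8.27e-04) or treated mutant replicate 2 (adjusted p = 0.00254). Myeloid markers had 0 of 12 past the threshold.

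The count of 23 was unstable. It fell to 2 without untreated mutant replicate 2, reached 57 without untreated wild-type replicate 1 and 47 without treated mutant replicate 2, and was 15, 9, 7, 6, 13 and 4 without untreated wild-type replicate 3, treated wild-type replicates 1, 2 and 3, untreated mutant replicate 1 and treated mutant replicate 3. With only the 6 mutant arrays in the fit, the count was 6, and 3 of these were among the 23. The main fit takes the spread of a gene from all 12 arrays. The count was 717 with array weights and 215 with replicate number as a block within each E12 form, the latter chosen after the data were seen. With that block Ccl4 (2.57 ± 0.27, adjusted p = 1.18e-04), Ccl3 (1.47 ± 0.17, adjusted p = 1.82e-04), Egr3 (1.33 ± 0.14, adjusted p = 1.18e-04) and Rel (0.66 ± 0.12, adjusted p = 0.0118) passed too. The calls of Trmt61a and Ephx1 held without any 1 of the 12 arrays, and that of Fam167a was lost without untreated mutant replicate 2.

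The difference of the anti-IgM responses asks whether E12 form changed how genes responded. Of the 371 genes that rose and the 324 that fell by at least 1 log2 unit with wild-type E12, 240 and 207 had a smaller response with the mutant past the threshold; choosing genes by their wild-type response favours this direction. Plau had responses of 2.83 with wild-type and 0.36 with mutant E12 (difference -2.46 ± 0.22 SE, n = 3 per group; adjusted p = 9.25e-05), and Srm of 2.65 and 0.55 (difference -2.10 ± 0.20, adjusted p = 9.25e-05). Irf4 had responses of 1.63 and -0.23 (difference -1.86 ± 0.40, adjusted p = 0.0133) and Myc of 1.64 and 0.08 (difference -1.56 ± 0.31, adjusted p = 0.00847). Ets1 had responses of -2.25 and -0.23 (difference 2.02 ± 0.30, adjusted p = 0.00180) and the chemokine receptor gene Ccr6 of -1.71 and 0.28 (difference 1.99 ± 0.29, adjusted p = 0.00156).

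The responses differed for 698 genes, with 350 positive and 348 negative differences. Of these, 689 had also passed in the wild-type response. Other large positive differences were those of Snx29 (2.41), Arhgef18 (2.18), Lrrk2 (2.02 ± 0.18), Rnase6 (1.94), the adaptor gene Sla (1.92), E2f2 (1.87), Fgd2 (1.75) and the interleukin 10 receptor gene Il10ra (1.72), and negative ones those of Rgcc (-2.35), the cytokine gene Csf1 (-2.10), Rgs1 (-1.89), Dusp2 (-1.85), Gch1 (-1.82), the chemokine gene Xcl1 (-1.74) and Pitrm1 (-1.67). Second probes for Snx29 (0.10), Lrrk2 (0.23 and 0.39) and Ets1 (0.28 and 0.08) did not pass. Nxpe2, named here after its values were seen, was the 1 gene called in both responses with opposite signs, at -0.64 with wild-type and 1.02 with mutant E12.

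**Figure D2:**
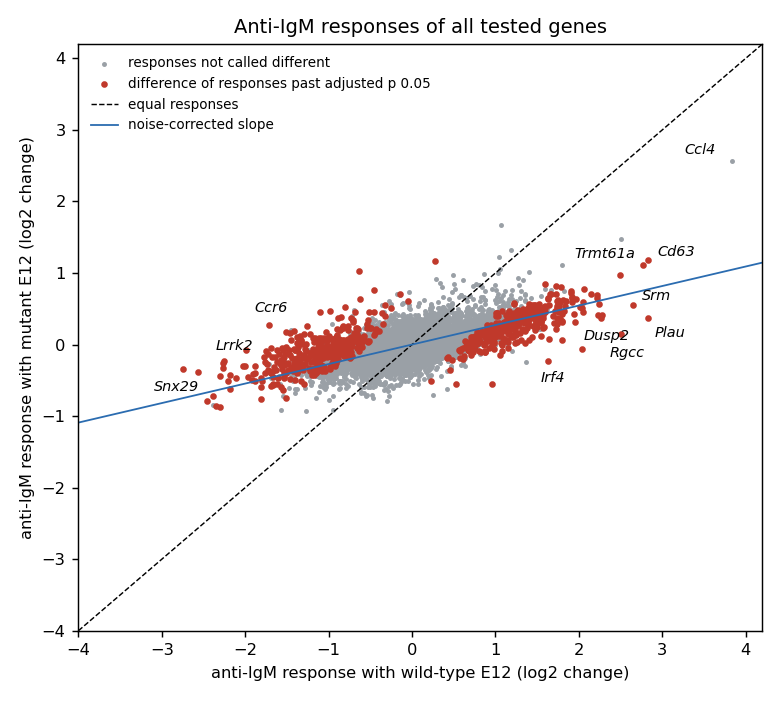
Log2 change with anti-IgM in mutant E12 cells against that in wild-type E12 cells for 10050 genes, with the 698 genes whose responses differed in red, a dashed line of equal responses and a solid line at the noise-corrected slope of 0.273. Most red points lie nearer 0 on the mutant axis than on the wild-type axis.

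Across genes, which are not independent replicates, the responses correlated with a Pearson r of 0.619 (jackknife SE 0.140) and a Spearman rho of 0.564 (SE 0.143), or 0.370 with no filter. Of the 3148 genes called with wild-type E12, 2722 (86.5%) had the same sign with the mutant. Their median change was 0.68 log2 units with wild-type E12 and, in the same direction, 0.17 with the mutant, and the noise-corrected slope was 0.273 ± 0.0639 (jackknife SE). In both forms 15 genes rose, against 2.88 by chance, and 4 fell, against 0.647 by chance. Ccl4 (difference -1.26, adjusted p = 0.370) and Ccl3 (-1.03, adjusted p = 0.169), both looked at here after their values were seen, did not differ in response past the threshold.

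By list, MYC and ribosome biogenesis genes had the largest difference, with 13 of 19 members more weakly induced with the mutant (17 adjusted over the list alone), 0 the other way and a median of -1.05 (adjusted p = 8.14e-16; adjusted p = 0.0176 with an estimated correlation). Examples were Nop58 (-1.56), Nop56 (-1.53) and Nop2 (-1.52). Antigen receptor genes had positive differences in 7 of 26 cases and negative in 0 (11 and 1 adjusted over the list alone), with Cd22 (1.51), Bank1 (1.36) and the phosphatase Ptpn6 (1.23, responses -0.46 and 0.77) as examples. Their median was 0.53 (adjusted p = 8.83e-05; adjusted p = 0.0200 with an estimated correlation), and Cd79b had a difference of 0.80 ± 0.20 (adjusted p = 0.0302). Its call was lost without untreated wild-type replicate 2 or 3 (adjusted p = 0.0753 and 0.0640), any treated wild-type replicate (0.0524, 0.0715 and 0.0917) or untreated mutant replicate 2 (0.0623). Interferon response genes had positive differences in 6 of 15 cases and negative in 0 (7 and 0 adjusted over the list alone), with Gbp2 (1.67), Gbp3 (1.42) and Mx2 (0.90). Their median was 0.28 (adjusted p = 7.29e-05; adjusted p = 0.0176 with an estimated correlation).

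Immediate early genes had negative differences in 6 of 23 cases and positive in 0, the same adjusted over the list alone, including Dusp2, Myc and Fosl2 (-1.48). Their median was -0.56 (adjusted p = 6.12e-05; adjusted p = 0.160 with an estimated correlation). Of 12 glycolysis genes 5 had negative and 0 positive differences (7 and 1 adjusted over the list alone), Ldha with -0.98 and Pgam1 with -0.97. Their median was -0.62 (adjusted p = 4.70e-04; adjusted p = 0.129 with an estimated correlation). B cell transcription factors had 9 positive differences and 1 negative among 24 (11 and 1 adjusted over the list alone), with Bcl11a (1.60) and Klf2 (1.57) beside Ets1, and Irf4 as the negative one. Their median was 0.27 (adjusted p = 0.00108; adjusted p = 0.166 with an estimated correlation). Of 17 stress genes 3 had negative differences and 0 positive (4 and 0 adjusted over the list alone), with Hspd1 at -1.16 and a median of -0.39 (adjusted p = 0.00195; adjusted p = 0.0572 with an estimated correlation). Of 25 cell cycle genes 3 had positive and 1 negative differences, the same adjusted over the list alone, with a median of 0.28 (adjusted p = 0.0359; adjusted p = 0.252 with an estimated correlation). That call was lost with detection on all 12 arrays (adjusted p = 0.0568) and on leaving out any 1 of 6 arrays: untreated wild-type replicate 3 (adjusted p = 0.0847), treated wild-type replicate 1 (0.119), untreated mutant replicates 2 and 3 (0.0813 and 0.0511), or treated mutant replicates 1 and 3 (0.0899 and 0.0827). Antigen presentation genes (median 0.21, adjusted p = 0.196) and apoptosis genes (median 0.10, adjusted p = 0.0716) were not called, but were without untreated wild-type replicate 1 (adjusted p = 0.00540 and 0.0493), as were the 3 stromal markers (0.0409). Apoptosis genes were also called without treated wild-type replicate 3 (adjusted p = 0.0435) or untreated mutant replicate 3 (adjusted p = 0.0497). E2A-associated targets had 5 positive and 2 negative differences among 19 (6 and 2 adjusted over the list alone; adjusted p = 0.402), with Gfi1 at -1.37 and Ccnd3 at 0.97, the latter with other probes at -0.13 and -0.09. Adgre1 (1.46) and Mpeg1 (1.68), the 2 of 12 myeloid markers with a positive difference, are markers raised in untreated wild-type replicate 1. Without that array 2 of 12 myeloid markers still had a positive difference and 0 a negative one, but the list's median turned from 0.11 to -0.15. The count does not say which markers these were. Adgre1 was also not detected in untreated mutant cells, so a fall there could not be measured. How far that array is the source is therefore left open.

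**Figure D3:**
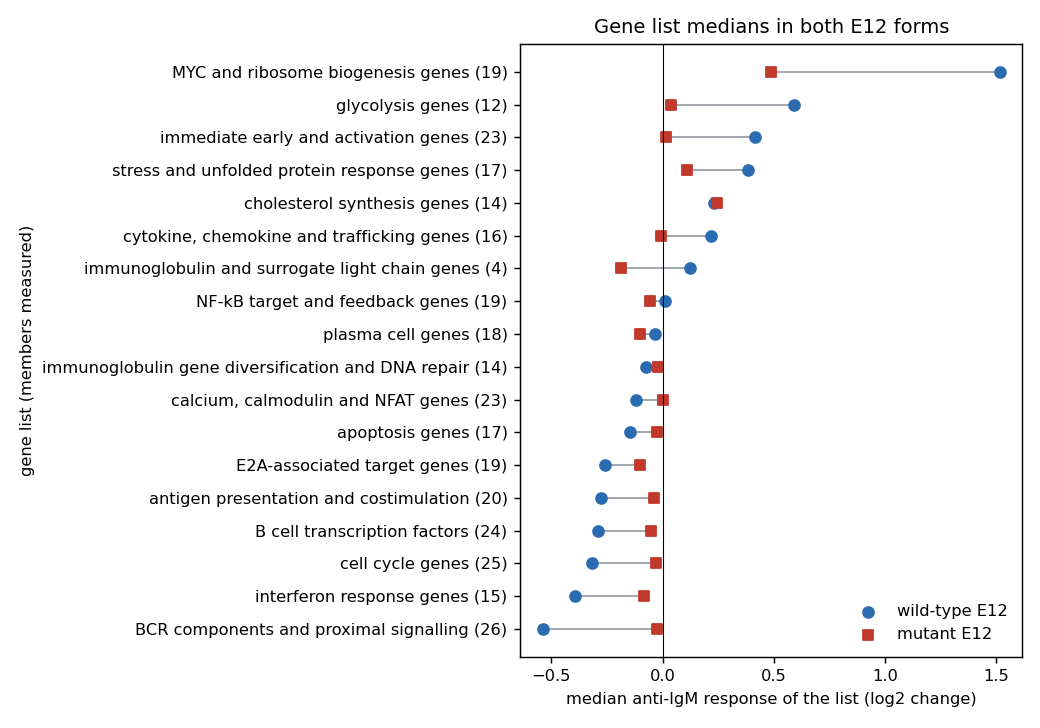
Median log2 change with anti-IgM of the 18 gene lists that are not cell type markers, in wild-type and mutant E12 cells, with the number of measured members in parentheses. The MYC and ribosome biogenesis list lies at 1.52 and 0.49, and the antigen receptor list at -0.54 and -0.02.

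The number of different responses depended on the arrays, the scaling and the model. It was 374, 430 and 456 without treated wild-type replicates 1, 2 and 3 and 424 without untreated mutant replicate 2, but 2327 with array weights and 1402 with replicate number as a block within each E12 form. It was 387 with arrays centred on their 75th percentile, 385 on the deposited values and 385 with cyclic loess. The block within each form and cyclic loess were chosen after the data were seen.

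The comparison of mutant with wild-type E12 in untreated cells shows what differed before the receptor was engaged. As lists, glycolysis genes were higher with the mutant and antigen receptor genes were lower (adjusted p = 0.0266 for each with an estimated correlation). The glycolytic enzyme Tpi1 was higher by 2.83 ± 0.17 log2 units (SE, n = 3 per group; adjusted p = 5.57e-08), Fkbp11, a secretory pathway prolyl isomerase, by 3.09 ± 0.18 (adjusted p = 4.64e-08) and the cytokine Il10 by 2.68 ± 0.33 (adjusted p = 2.29e-05). Cd72, an inhibitory B cell coreceptor, was lower (-3.09 ± 0.27, adjusted p = 1.07e-06), as was Zfp318, a nuclear factor needed for IgD expression (-3.10 ± 0.16).

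In all, 4283 of 10050 genes differed, 2050 higher and 2233 lower with the mutant, 470 and 546 of them by at least 1 log2 unit. The arrays of the 2 forms did not overlap for 4959 of the 10050 genes. Further genes higher with the mutant were Ly6c1 (3.20 ± 0.32), thyroglobulin Tg (3.00), the inhibitory receptor Ctla4 (2.99), Oosp1 (2.94), Pinlyp (2.88), the oxygen-sensing prolyl hydroxylase Egln3 (2.75) and Plpp5 (2.72). Lower were Ccdc144b (-4.22 ± 0.16), Hivep3 (-3.64), Rhbdl2 (-3.38), Lbh (-3.20), Erich5 (-3.20), Snn (-3.16, with other probes at -0.34 and -0.19) and Zxda (-3.11). The calcium channel Ryr2 was at least 9.73-fold lower.

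Of 12 glycolysis genes 11 were higher and 0 lower, the same adjusted over the list alone, with Tpi1, Slc2a1 (2.00) and Aldoa (1.97) as examples. The median was 1.67 (adjusted p = 3.94e-09; adjusted p = 0.0266 with an estimated correlation). Of 18 plasma cell genes 14 were higher and 2 lower, the same adjusted over the list alone, with Fkbp11 and the secretory pathway genes Derl3 (2.45), Creld2 (2.23) and Sec61b (2.07). The median was 0.89 (adjusted p = 5.32e-06; adjusted p = 0.261 with an estimated correlation). Of 25 cell cycle genes 17 were higher and 1 lower, the same adjusted over the list alone, among them the mitotic genes Cdc20 (1.48), Plk1 (1.37) and Birc5 (1.26). The median was 0.65 (adjusted p = 7.00e-05; adjusted p = 0.0854 with an estimated correlation).

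Antigen receptor genes were lower in 19 of 26 cases and higher in 3, the same adjusted over the list alone: Cd72, Cd22 (-2.32), Ptpn6 (-2.06) and the kinase Blk (-1.66) led the list, with single further probes for Cd22 (-0.34) and Blk (-0.19) not past the threshold. The median was -0.70 (adjusted p = 7.00e-05; adjusted p = 0.0266 with an estimated correlation). Cd79b was at -0.65 ± 0.14 (adjusted p = 0.00244), but at 0.33 after centring on the 75th percentile and 0.27 on the deposited values. Of 24 B cell transcription factors 13 were lower and 3 higher (15 and 3 adjusted over the list alone), with Bcl11a (-2.25), Irf8 (-2.24), Pou2f2 (-2.20) and Bcl6 (-1.80). The median was -0.53 (adjusted p = 5.13e-04; adjusted p = 0.213 with an estimated correlation). Of 14 cholesterol synthesis genes 8 were lower and 1 higher, the same adjusted over the list alone, including Msmo1 (-2.07), Sqle (-1.83), Dhcr7 (-1.22) and Lss (-2.11, with another probe at 0.00432). The median was -0.78 (adjusted p = 0.00484; adjusted p = 0.426 with an estimated correlation). Of 19 NF-kB target genes 10 were lower and 4 higher (11 and 4 adjusted over the list alone), with Nfkbiz (-1.50) and Nfkbie (-1.28). The median was -0.42 (adjusted p = 0.0331; adjusted p = 0.137 with an estimated correlation). That call was lost with detection on all 12 arrays (adjusted p = 0.0804), after centring on the 75th percentile (adjusted p = 0.0921), on the deposited values (adjusted p = 0.125) and without untreated wild-type replicate 3 (adjusted p = 0.0504).

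MYC and ribosome biogenesis genes were not called in untreated cells, with 3 of 19 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.890); the median of -0.03 and the mean of 0.04 differed in sign. Srm was higher (1.13), and Npm1 was at -0.87 but at 0.16 and 0.11 under the other scalings. E2A-associated targets were lower in 8 of 19 cases and higher in 2, the same adjusted over the list alone (adjusted p = 0.0868, or 0.0182 with no filter), with the chemokine receptor Cxcr4 at -1.39. Among stress genes 5 of 17 were higher and 2 lower (6 and 2 adjusted over the list alone), with the amino acid response genes Asns (2.37), Chac1 (1.96) and Trib3 (1.68), and the list was called after centring on the 75th percentile (adjusted p = 0.0116) and on the deposited values (adjusted p = 0.0122). Antigen presentation genes were lower in 10 of 20 cases and higher in 5 and were called without untreated wild-type replicate 1 (adjusted p = 0.0208 against 0.141). Of 12 myeloid markers 6 were lower and 1 higher: Lyz1 (-2.11), Lyz2 (-1.66, detected on 1 of 3 mutant arrays) and Adgre1 (at least 4.07-fold lower) against Ly6c1, which lymphocytes also express. Untreated wild-type replicate 1 held the highest Lyz1 and Lyz2 of all 12 arrays. Even the lowest wild-type Lyz1, at 8.15, lay above the highest mutant value of 7.33, so that array alone does not account for the difference in Lyz1.

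**Figure D4:**
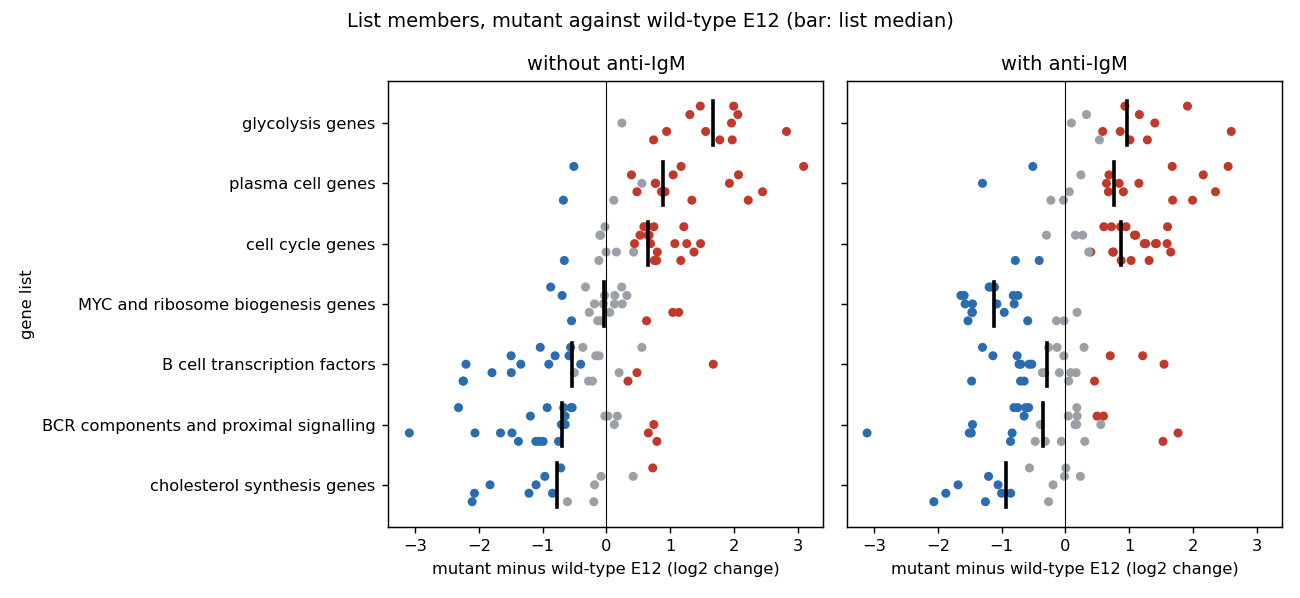
Log2 difference of mutant minus wild-type E12 for members of 7 gene lists, without and with anti-IgM, coloured red or blue where higher or lower past the threshold and grey otherwise, with a bar at each list's median. Glycolysis genes have a median of 1.67 without and 0.97 with anti-IgM.

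The share of calls that were higher with the mutant was 47.9%, but 66.8% on the deposited values and 72.2% after centring on the 75th percentile, with the median of all genes at 0.01, 0.13 and 0.18 log2 units. The authors' separate normalization of the E12 forms and any separate run of them cannot be told apart from E12 form, and the differences correlated with gene span across genes (Spearman rho -0.178), which are not independent replicates. Xist was at 8.69 and 6.78 in untreated mutant replicates 2 and 3 and at 5.52 to 5.63 in untreated wild-type arrays. The wild-type values lie under the detection limit, as does that of untreated mutant replicate 1 (5.56). Xist signal was thus present with the mutant only, in replicates 2 and 3. The mixture of male and female cells therefore most likely differed between the forms, partly along with E12 form, and this was not modelled.

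With anti-IgM, the comparison of mutant with wild-type E12 shows the state reached after 3 h. Cd63 was lower (-4.25 ± 0.19 log2 units, SE, n = 3 per group; adjusted p = 1.97e-08), as were Dusp2 (-2.82 ± 0.19) and Cd72 (-3.11 ± 0.27). Txnip, an inhibitor of glucose uptake, was higher by 2.68 ± 0.19 (adjusted p = 1.42e-07), Egln3 by 3.07 ± 0.34 and Tpi1 by 2.60 ± 0.17.

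In all, 4368 genes differed, 2136 higher and 2232 lower, 599 and 547 of them by at least 1 log2 unit, and the arrays of the 2 forms did not overlap for 5840 of the 10050 genes. Higher with the mutant were also Oosp1 (3.27), Abi3 (3.10), Sla (3.03), Tg (3.03), Ly6c1 (2.97), Edem2 (2.87), Ankrd37 (2.81) and Ctla4 (2.75). Lower were Hivep3 (-3.03), Lbh (-2.91), Ccdc144b (-2.84), Dpp7 (-2.78), Ppargc1b (-2.66), the neuronal enolase Eno2 (-2.64) and Myo1e (-2.53, with another probe at -0.01). Cd79b did not differ past the threshold (0.15, adjusted p = 0.435), and Ebf1 was lower (-0.57, adjusted p = 0.00370).

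MYC and ribosome biogenesis genes were lower in 16 of 19 cases and higher in 0, the same adjusted over the list alone, with Rrp12 (-1.64), Nop58 (-1.59) and Nop56 (-1.57). The median was -1.11 (adjusted p = 2.42e-07; adjusted p = 0.0731 with an estimated correlation). Cell cycle genes were higher in 19 of 25 cases and lower in 2, the same adjusted over the list alone, with Plk1 (1.65) and Birc5 (1.59). The median was 0.87 (adjusted p = 5.56e-07; adjusted p = 0.0731 with an estimated correlation). Glycolysis genes were higher in 9 of 12 cases and lower in 0 (10 and 0 adjusted over the list alone), with Pdk1 (1.91) and Pgk1 (1.40) beside Tpi1. The median was 0.97 (adjusted p = 7.03e-06; adjusted p = 0.0731 with an estimated correlation). Plasma cell genes were higher in 12 of 18 cases and lower in 2, the same adjusted over the list alone, with Fkbp11 (2.55) and Derl3 (2.35). The median was 0.76 (adjusted p = 1.80e-04; adjusted p = 0.405 with an estimated correlation). Cholesterol synthesis genes were lower in 8 of 14 cases (9 adjusted over the list alone) and higher in 0, with Msmo1 (-1.88) and Sqle (-1.68). The median was -0.93 (adjusted p = 0.00137; adjusted p = 0.405 with an estimated correlation). NF-kB target genes were lower in 12 of 19 cases and higher in 3 (12 and 4 adjusted over the list alone), with Nfkbie (-1.73) and the cytokine Tnf (-1.68). The median was -0.57 (adjusted p = 0.0174; adjusted p = 0.0883 with an estimated correlation), and on the deposited values the call was lost (adjusted p = 0.0614).

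Interferon response genes were higher in 9 of 15 cases and lower in 1 (9 and 2 adjusted over the list alone), with Gbp2 (1.60) and Bst2 (1.40), but the list was not called (median 0.49, adjusted p = 0.0635). It was called with no filter (adjusted p = 0.0322), with detection on all 12 arrays (0.0427), with every probe tested (0.0372) and without treated wild-type replicate 1 (0.0468) or treated mutant replicate 3 (0.0484). Antigen receptor genes were lower in 11 of 26 cases and higher in 4, the same adjusted over the list alone (adjusted p = 0.240), with the adaptor Dapp1 (1.53) and the inhibitory Fc receptor Fcgr2b (1.77) among the higher. Immediate early genes were lower in 9 of 23 cases and higher in 3, the same adjusted over the list alone (adjusted p = 0.108, or 0.0494 without treated mutant replicate 3), with Egr2 at -2.32. Of 12 myeloid markers 2 were higher, Ly6c1 and Mpeg1 (2.02), and 4 lower, Lyz1 (-1.69) and Lyz2 (-1.25, detected on 1 of 3 mutant arrays) among them.

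The share of calls that were higher was 48.9%, but 67.4% on the deposited values and 72.8% after centring on the 75th percentile, with the median of all genes at -0.01, 0.11 and 0.17. As without anti-IgM, a run of the arrays cannot be told apart from E12 form.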

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

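All tests of the smaller response below were chosen after the result was seen, except the one on genes with equal levels in untreated cells, and so was the count of splits with each form's mean taken out. The response to anti-IgM differed between the 2 E12 forms, by the interaction test of limma, for 698 genes. Among the genes named for it, the difference (mutant minus wild-type response, log2) was positive for Snx29 (2.41), Arhgef18 (2.18), Ets1 (2.02), Lrrk2 (2.02), Ccr6 (1.99), Rnase6 (1.94), Sla (1.92), E2f2 (1.87), Fgd2 (1.75) and Il10ra (1.72). It was negative for Plau (-2.46), Rgcc (-2.35), Csf1 (-2.10), Srm (-2.10), Rgs1 (-1.89), Irf4 (-1.86), Dusp2 (-1.85), Gch1 (-1.82), Xcl1 (-1.74) and Pitrm1 (-1.67). Each value is from a single probe, and the other probes for Snx29, Lrrk2 and Ets1 did not pass, as given above. By limma's camera on the same interaction term, 8 lists differed between the forms, with median differences of 0.53 for antigen receptor genes, 0.27 for B cell transcription factors, 0.28 for cell cycle genes, 0.28 for interferon response genes, -0.56 for immediate early genes, -1.05 for MYC and ribosome biogenesis genes, -0.62 for glycolysis genes and -0.39 for stress genes. With an estimated correlation, antigen receptor (adjusted p = 0.0200), MYC and ribosome biogenesis (0.0176) and interferon response genes (0.0176) kept their call. For B cell transcription factors adjusted p = 0.166 with an estimated correlation, for immediate early genes 0.160, cell cycle genes 0.252, glycolysis genes 0.129 and stress genes 0.0572.

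The pattern weighed is the smaller response with mutant E12. Swapped treatment labels among the mutant arrays would bring treated and untreated arrays together on the genes of the wild-type response, but the lowest treated array lay 0.389 above the highest untreated 1. A larger spread among the mutant arrays would cost calls and leave the sizes of the changes, but the noise-corrected slope was 0.273; over 6 scalings of the arrays the slope reached at most 0.325. Genes with a baseline difference under 0.25 had a slope of 0.310, which argues against levels already shifted in untreated mutant cells as the whole cause, but they may play a part for other genes: of the 689 genes called for both the difference and the wild-type response, 326 were already shifted in untreated mutant cells the way anti-IgM moved wild-type cells, and 92 the other way, a balance to which the shared untreated wild-type arrays add. A separate run of the mutant arrays cannot be told apart from E12 form, since 0 sets of arrays hold both, and the higher Tcf3 signal with the mutant stays open beside the mutation itself.

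Other splits of the samples were counted for each comparison. For 3 against 3 arrays there are 10 splits, so a share under 0.05 cannot be reached and the smallest is 0.1. These splits exchange arrays without regard to replicate number, which may pair some of them. The real split alone, 1 of 10, gave as many genes in the wild-type response (3148, highest other 0), in untreated cells between forms (4283, highest other 0) and with anti-IgM between forms (4368, highest other 0). In the mutant response 2 of 10 splits gave at least the 23 genes of the real one, and the other called 1256, which points to a structure of the mutant arrays. For the difference of responses, 100 of the 200 possible splits of the E12 forms were run, so the shares are estimates. Of these 100, 5 gave at least 698 genes, with 5609 in the highest other, so chance is not excluded by this count. The 4 others exchanged the forms wholly or mostly among the untreated or the treated arrays. Differences between the forms thereby entered the interaction. With the mean of each form taken out first, 1 of 100 did, and the highest other gave 0. With the means out, however, a whole exchange of the forms among the untreated or the treated arrays gives an interaction of 0 by construction. This second count therefore does not exclude chance either.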

How the results depend on the processing

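The offsets, cyclic loess and the replicate block within each E12 form were chosen after the data were seen. Planned settings not run were no background correction and normexp in place of neqc, since the values were already background-subtracted, and slide as a block, since no slide is given. For the changes below, the cause was not tested, except that testing every probe adds features, a fold limit removes small changes and fewer arrays lower the residual degrees of freedom. The signal over background limits what can be said of dim genes, whose changes the offset shrinks.

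Testing every probe gave 5326 calls in the wild-type response, 8168 between forms in untreated cells and 7907 with anti-IgM, and a fold of at least 1.5 left 1980, 2717 and 2842. Array weights gave 5196 calls in the wild-type response, 717 in the mutant response and 2327 for the difference. The mutant response had 37 calls with no filter, 50 with 75th-percentile centring, 49 on the deposited values and 51 with cyclic loess. It had 6 with only the 6 arrays compared, of which 3 were among the 23, and 2 to 57 with 1 array left out. The difference had 387 with 75th-percentile centring, 385 on the deposited values and 385 with cyclic loess, all among the 698, and 374 to 810 with 1 array left out. With no filter, the Spearman correlation of the responses across genes was 0.370.

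Replicate number as 1 block over both forms gave 3145, 25, 703, 4288 and 4366 calls in the order of the comparisons. As a block within each form it gave 3929 in the wild-type response, 215 in the mutant response, with all 23 among them, and 1402 for the difference. In the wild-type response, where pairing by number was clear for replicate 1 only, it added the call of Id3. It changed that of no other gene or list named for that response. Among mutant arrays the numbers did not pair by the correlation of deviations, and with it 11 more of the genes named for the mutant response passed: Ccl4, Ccl3, Egr3, Rel, Atf3 (adjusted p = 0.00421), Gbp2 (0.00961), Ddit3 (0.0358), Cd86 (0.0395), Ikzf3 (0.0439), Bcl2l1 (0.0459) and Gbp3 (0.0493). Genes named for other comparisons passed there too, among them Ptpn6 (0.00580), Cd72 (0.00626) and Nop58 (0.0391). Among the genes and lists named for the difference, the block added Insig1 (0.0199), Il7r (0.0262), Prf1 (5.23e-04) and the apoptosis list (0.0465).

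The direction in untreated cells between forms reversed for Cd79b (0.33 with 75th-percentile centring, 0.27 on the deposited values), Npm1 (0.16 and 0.11), Hspa8 (0.33 and 0.28) and Ppp3r1 (0.035 with 75th-percentile centring). Of the calls of named genes, 4098 were kept over the settings that used all arrays, 155 were no longer past the threshold and 7 reversed; with 1 array left out, 3939 were kept and 261 were not. Of the calls of lists, 375 were kept and 7 were not, and with 1 array left out 361 and 11. With detection on all 12 arrays the calls lost were those of cell cycle genes in the wild-type response (adjusted p = 0.0588) and the difference (0.0568) and of NF-kB targets between forms in untreated cells (0.0804). Array weights lost that of cholesterol synthesis in the mutant response (0.0933). Lists gained calls too. With no filter these were antigen presentation (adjusted p = 0.0399) and cholesterol synthesis (0.0196) in the wild-type response, apoptosis in the difference (0.0321), E2A-associated targets (0.0182) and antigen presentation (0.0219) between forms in untreated cells, and immediate early (0.0335) and interferon response genes (0.0322) with anti-IgM. Array weights added antigen presentation in the wild-type response (0.0407) and the difference (0.0499) and apoptosis in the difference (0.0336). Testing every probe added apoptosis in the difference (0.0346) and interferon response between forms with anti-IgM (0.0372), and detection on all 12 arrays the latter (0.0427). Stress genes were called between forms in untreated cells with 75th-percentile centring (0.0116) and on the deposited values (0.0122).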

Other observations

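All tests in this part were chosen after the result was seen, except that of the hypoxia genes, whose values had not been seen. Long noncoding RNAs varied among the arrays. Neat1, a long nuclear RNA, was at 10.13 to 10.79 log2 units in untreated wild-type arrays and at 7.37 to 9.30 in untreated mutant arrays. Xist, the RNA of the inactive X chromosome, was at 5.56 and 5.58 in mutant replicates 1, at 8.69 and 9.12 in replicates 2 and at 6.78 and 6.56 in replicates 3, untreated and treated. In the 6 wild-type arrays Xist was at 5.37 to 5.66, under the detection limit, as were the values of mutant replicates 1. Eif2s3y, a gene of the Y chromosome, was at 9.57 to 10.28 in wild-type and at 8.55 to 9.58 in mutant arrays.

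A hypothesis on the higher glycolysis genes with mutant E12 is less oxygen in those cultures. Of 28 other hypoxia-inducible genes, a list outside the fixed ones, 23 were measured; in untreated cells 10 were higher and 3 lower with the mutant, with Fam162a at 1.76, P4ha1 at 1.40, Ak4 at 1.31, Pfkfb4 at -1.47 and Wsb1 at -1.41. Their median of 0.32 lay above 99.93% of 10000 random lists of the same size and expression (5th to 95th percentile -0.16 to 0.18), and that of 0.35 with anti-IgM above 99.94%. The members did not move alike: in untreated cells Ndrg1 was also lower (-0.95), and Car9 (-0.27), Slc16a3 (0.08) and Vegfa (0.51) did not pass. With anti-IgM Fam162a was at 0.42 and did not pass. Random lists also carry no correlation between genes that move together. Less oxygen may have been present, but a run of the arrays and the E12 mutation itself stay open, and no oxygen measurement was used here.

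The pattern of myeloid transcripts in untreated wild-type replicate 1 had been noticed through Lyz1 (10.45 against a mean of 8.61 in the other 2) and Lyz2 (8.82 against 7.21), so the median of all 12 measured markers, above 100% of 10000 random lists, decides nothing. The 10 other markers had a median deviation of 0.36, above 99.96% of random lists of the same size and expression (95th percentile 0.17), and 7 were higher than in both other arrays. Adgre1 (1.07) and Mpeg1 (0.86) deviated most, but the broad myeloid genes Fcer1g (-0.17), Tyrobp (-0.08) and Cybb (-0.01) were not higher, and Csf3r, Cd33 and S100a8 were detected on only 1 of the 3 untreated wild-type arrays. RNA of myeloid cells that passed the GFP sort may account for a part of this, which these values do not decide; no biological explanation was tested. Without this array the wild-type response had 2854 calls, 2551 of them among the 3148, the mutant response 57, the difference 757 and the comparison of forms in untreated cells 3951.

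The pattern behind the split that called 1256 genes is an axis shared by the mutant arrays, with 64.7% of the variance of their deviations. Untreated replicates 1 and 2 and treated replicate 1 lay on 1 side and the other 3 on the other, with Neat1 at 7.09 to 7.68 and at 8.70 to 9.30. The deviations correlated with gene span across genes, which are not independent replicates, by at least 0.163 in size in each of the 6 mutant arrays, so RNA length or quality may be a part of the axis. Different mixtures of male and female cells stay open: the arrays with the highest Xist of their groups lay on opposite sides (product of signs -1), but Xist was among the 20 named genes highest at 1 end of the axis. Egr1, Fos and Dusp1 of the immediate early list were at the same end. The axis therefore adds to the spread of that list among the mutant arrays. Xist differed by at most 0.43 within a replicate number and by at least 0.98 between single arrays of different numbers, a hint that same-numbered mutant arrays may share animals.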
